A study of Homo sapiens with 9 samples.

How the data were processed

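RNA of HTR8/SVneo cells had been sequenced in 9 libraries, 3 for each of the PBS, H/R and pAKK+H/R groups, with a SMARTER mRNA kit per the labels. The deposited values are raw read counts per gene, 1 table per library, which the authors made before deposit with FastQC, Bowtie2, SAMtools and HTSeq per the labels. The labels name these tools without role, order or version and give hg19 as the genome build. The annotation release and the strand setting were not given in the sources used here, so reads of overlapping or adjoining genes on opposite strands, such as MT-ND6 and MT-ND5, may be divided in a way that cannot be checked. The values were tested on the files to be whole numbers, and each table ended with HTSeq's 5 summary lines, which were set aside from the gene counts. The tables held 57773 gene identifiers and 95 spike-in or reporter entries, which had 1 count in total. Names came from a reference name table for 39538 identifiers and from GENCODE 29 for another 12784, and 5451 had none. GENCODE 29 lies on another build than the counts, so it served only for names, gene types, neighbours, GC content and transcript length, and no positions are given.

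Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were filtered with filterByExpr, which left 15991 genes, 13180 of them protein coding. Libraries were scaled by TMM (factors 0.939 to 1.12), all 9 were fitted in 1 quasi-likelihood model with a common dispersion of 0.0415, and each pair of groups was compared with Benjamini-Hochberg adjustment at 0.05. Levels are CPM scaled by TMM, except those of the genes counted almost only in H/R and of immune genes, which are CPM of all gene counts without that scaling. Folds come from the fitted model, not from the ratio of mean CPM. Where a group had 1 to 3 counts of a gene, the ratio is given with its 95% counting interval. Such intervals cover counting error only.

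The 40 gene lists were tested with camera in limma 3.58.1 on log2 CPM with a prior count of 2, a preset correlation of 0.01 and at least 5 tested members, and again with an estimated correlation and with fry. They held 853 genes, of which 847 were matched. Lists, comparisons, main settings and most alternatives were fixed before the data were examined. The genes named were those with the highest or lowest log2 fold changes past the test with a mean of at least 2 CPM and group ranges that did not overlap, list members with the smallest p, a fixed panel, and the genes moved back with the largest product of changes. The other genes named, such as TFRC, IGFBP3 and DIO2 in the comparison of H/R with PBS, were followed there because another comparison named them, after their values were seen. Of the 28 panel genes, 23 were tested, and IL6, TLR2, TLR4, PPARGC1A and HLA-G were too low to test.

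On simulated data with 200 genes made to differ among 15656, the test called 43.3% of 2-fold changes in the comparison of H/R with PBS and 45.4% in that of pAKK+H/R with H/R, and 3.06% and 2.04% of 1.5-fold changes, so most small changes are missed with 3 libraries per group. The overlap of the comparisons was set against 50 simulated data sets of each of 2 kinds. The alternatives were other scalings, DESeq2 1.42.0, limma-voom, no filter, a mean of at least 50 counts, a log2 fold change of at least 1, 2-group fits, leaving out each library in turn, removing a trend on GC content and length (lowess span 0.3, with both known for 97.3% of tested genes), and leaving out HR 1 and pAKK_HR 1 together. No paired analysis was possible because the labels give no pairing.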

Results

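Gene counts were obtained from 9 RNA sequencing libraries of HTR8/SVneo cells, an established human trophoblast line. The libraries formed 3 groups of 3. The PBS group was the control, but the labels do not say how its cells were held during the hypoxia of the other groups, which bears on every difference from PBS. The H/R group was held in 2% O2 for 8 h and then reoxygenated for 16 h. The pAKK+H/R group received pasteurized Akkermansia muciniphila, a gut bacterium, for 24 h and then the bacterium together with hypoxia and reoxygenation for another 24 h. The series names preeclampsia and mitochondrial, apoptotic damage of the placenta as its subject. The gene counts summed to 15710698, 19135447 and 14453260 in PBS 1 to 3, to 19010581, 17440058 and 17370483 in HR 1 to 3, and to 15621932, 20745296 and 18213365 in pAKK_HR 1 to 3. These numbers only name the libraries and do not pair them. Nothing in the labels says whether the 3 libraries of a group came from separate cultures, so p-values measure the spread between these samples, which may be technical. No group received the bacterium without hypoxia. A first 24 h before hypoxia is recorded for the pAKK+H/R group only, so time in culture may differ from the H/R group along with the bacterium.

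The first principal component of 15991 genes held 37.3% of the variance and placed the pAKK+H/R libraries between the PBS and H/R libraries, nearer to PBS. Positions on it were -30.6 to -32.7 in PBS, 45.4 to 49.4 in H/R and -10.0 to -20.9 in pAKK+H/R. Libraries of a group also lay apart. pAKK_HR 1 lay at -63.7 on the second component (21.5% of the variance), and HR 1 lay at -43.0 on the third (12.8%), where HR 2 lay at 35.3 on the opposite side and the other libraries between -17.4 and 12.9. Genes of the mitochondrial genome took 8.35% of the gene counts in pAKK_HR 1 and 2.96% in HR 1, against 4.06% to 5.53% in the other libraries. More genes had at least 1 count in H/R, 26387 to 27502 per library against 21414 to 23113 in the other groups. The ranges did not overlap, and the exact permutation test of H/R against PBS gave a two-sided p of 0.1, the smallest that 3 against 3 libraries allow.

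**Figure D1:**
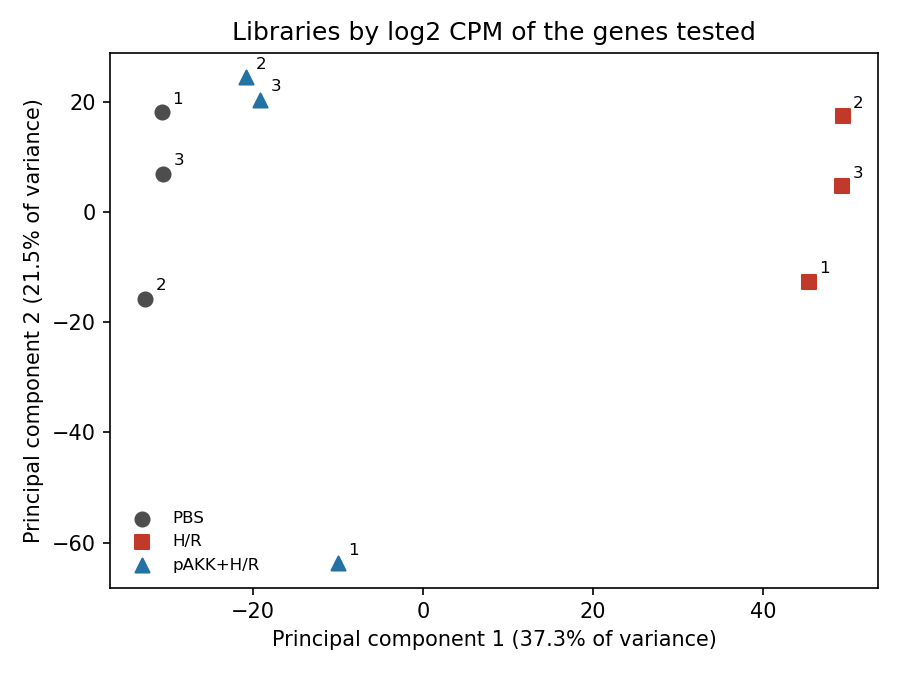
Position of each library on the first and second principal components of log2 CPM over 15991 genes; axis units are component scores, points are libraries, colours and marker shapes are groups, and digits are library numbers. H/R libraries lie at 45.4 to 49.4 on the first component and pAKK+H/R libraries at -10.0 to -20.9, while pAKK_HR 1 lies at -63.7 on the second.

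The comparison of H/R with PBS asked what hypoxia followed by reoxygenation did to the transcripts of these cells. THBS1 (ENSG00000137801.9), the matrix glycoprotein thrombospondin 1, rose 11.9-fold, from 20.2 ± 2.84 CPM (counts-per-million) in PBS to 241 ± 67.8 CPM in H/R (SD, n = 3 per group). The growth factor gene TGFB2 (ENSG00000092969.7) rose 35.6-fold, from 0.629 ± 0.335 to 22.3 ± 3.18 CPM, and SERPINE1 (ENSG00000106366.7), an inhibitor of plasminogen activation, rose 5.57-fold, from 14.7 ± 7.66 to 81.4 ± 4.35 CPM. SFRP1 (ENSG00000104332.7), a secreted antagonist of Wnt signalling, fell 6.22-fold, from 167 ± 46.6 to 26.7 ± 3.69 CPM. The interferon-induced gene IFIT1 (ENSG00000185745.8) fell 5.41-fold, from 11.5 ± 1.17 to 2.14 ± 0.35 CPM.

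In edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 2009 of 15991 genes (12.6%) changed between PBS and H/R. Of these, 1003 were higher and 1006 lower in H/R, and 442 and 362 of them differed at least 2-fold. Scaling by library size alone split the calls into 1168 higher and 658 lower. Beside THBS1 and TGFB2, the genes that rose by large log2 factors included NIBAN3 at 6.41, the fibrillin gene FBN3 at 5.21, RBPJL at 5.05 and the calcium channel genes CACNA1A at 5.53 and RYR1 at 4.82. ZAN had 302 counts over the H/R libraries and 2 over the PBS libraries, a ratio of 131 with a 95% counting interval of 35.8 to 1080. NPHS1, the gene of the kidney slit diaphragm protein nephrin, had 432 counts against 3, a ratio of 124 with an interval of 42.3 to 606. ZAN, NPHS1, CACNA1A and RBPJL belonged to 290 genes counted almost only in the H/R libraries. Genes that fell included the collagenase gene MMP1 at a log2 fold change of -2.95, CALHM3 at -3.08, NTNG2 at -2.67, VAT1L at -2.55, OLFML3 at -2.37 and ADAMTSL1 at -2.34, of which MMP1 did not pass with limma-voom (adjusted p 0.0591). The iron uptake receptor gene TFRC rose 3.90-fold, the insulin-like growth factor binding protein gene IGFBP3 4.56-fold and the thyroid hormone deiodinase gene DIO2 9.43-fold.

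Of 20 genes of the TGF-beta response, 9 rose in H/R, 0 fell and 11 did not pass the test, with 10 and 0 adjusted over the list alone. They included THBS1 (3.58 on the log2 scale), the matrix-associated growth regulator CCN2 (1.99), SERPINE1 (2.48) and PMEPA1 (1.09), and the camera gene set test gave an adjusted p of 0.000325 (adjusted p = 0.274 with an estimated correlation). Of 23 cholesterol synthesis genes, 10 fell and 0 rose, or 13 and 0 adjusted over the list alone (camera adjusted p = 6.51e-06, and adjusted p = 0.386 with an estimated correlation). They included HSD17B7 at -1.20, the mevalonate kinase gene MVK at -1.27, the sterol reductase gene TM7SF2 at -1.28 and the lanosterol synthase gene LSS at -0.77. Of 25 type I interferon response genes, 9 fell and 0 rose, or 10 and 0 adjusted over the list alone, among them OASL at -3.11, IFIT1 at -2.44 and IFI6 at -1.24 (camera adjusted p = 0.000121, and adjusted p = 0.696 with an estimated correlation). The metal-binding metallothionein list had 5 genes tested, of which 4 rose, also 4 adjusted over the list alone (camera adjusted p = 0.00171, and adjusted p = 0.386 with an estimated correlation). The 4 were SLC30A1, a zinc exporter rather than a metallothionein, at 1.71, MT1F at 2.32, MT1E at 1.06 and MT2A at 0.79. Metallothionein genes are near-identical copies, so the division of reads among them is uncertain. Without PBS 1 or PBS 3, MT1F no longer passed (adjusted p 0.0538 and 0.0557), MT1E did not without PBS 3 (adjusted p 0.0625), and MT2A did not without any of PBS 1 to 3, HR 2 or HR 3 in turn (adjusted p 0.0807 to 0.140 by edgeR).

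The hypoxia-responsive regulator HIF1A rose 1.68-fold in H/R, from 162 ± 18.6 to 273 ± 9.47 CPM (edgeR adjusted p = 0.0149), and did not pass without PBS 1, PBS 2 or HR 3 in turn (adjusted p 0.0532 to 0.0786). Of 30 targets of the HIF factors, 3 rose and 2 fell, also 3 and 2 adjusted over the list alone (camera adjusted p = 0.523). The angiopoietin-like gene ANGPTL4 rose, at 1.69 on the log2 scale, while the stress-response gene DDIT4 fell, at -2.02, and the glycolytic regulator PFKFB4 fell, at -1.09; ANGPTL4 did not pass without PBS 1 or PBS 3 (adjusted p 0.0557 and 0.0563). Of 19 genes that promote intrinsic apoptosis, PMAIP1 alone rose, at 0.66, and 0 fell (camera adjusted p = 0.400; the same numbers adjusted over the list alone). BAX at -0.37, CASP3 at 0.38, CASP9 at -0.43 and the cytochrome c gene CYCS at 0.59 did not pass the test. CYCS passed in 7 of 22 alternatives, among them DESeq2 (adjusted p 0.0305) and library size alone (adjusted p 0.0254). It also passed without HR 1 or pAKK_HR 1 (adjusted p 0.0174 and 0.0354). Without both of these libraries CYCS and CASP3 passed (adjusted p 0.000229 and 0.0197). Of 12 genes that oppose apoptosis, BIRC2, XIAP and MCL1 rose and 0 fell, at 0.71, 0.62 and 0.48, or 3 and 1 adjusted over the list alone (camera adjusted p = 0.523). PMAIP1 lost its call without any PBS library, HR 2 or HR 3 in turn (adjusted p 0.0514 to 0.120), BIRC2 without PBS 1 (adjusted p 0.0513), XIAP without any PBS library or HR 3 (adjusted p 0.0734 to 0.154) and MCL1 without any PBS library, HR 1, HR 3, pAKK_HR 2 or pAKK_HR 3 (adjusted p 0.0579 to 0.155). With a trend on GC content and length removed, an alternative chosen after the data were seen, PMAIP1, BIRC2 and XIAP did not pass either, at 0.33, 0.41 and 0.37 (adjusted p 0.233, 0.0668 and 0.197). Nor did PMAIP1 and MCL1 without a filter on low counts (adjusted p 0.104 and 0.0995).

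Mitochondrial transcripts of nuclear and mitochondrial origin were counted separately. Of 13 protein genes of the mitochondrial genome, 2 fell in H/R and 0 rose, or 3 and 0 adjusted over the list alone, and 0 of the 13 had a log2 fold change above 0 (camera adjusted p = 0.00285, and adjusted p = 0.696 with an estimated correlation). MT-ND6 and MT-ND5 fell, at -0.93 and -0.67. MT-ND6 lost its call without PBS 1, PBS 2 or HR 3 in turn (adjusted p 0.0659 to 0.0779), and MT-ND5 without any library of PBS or H/R, or without pAKK_HR 3 (adjusted p 0.0526 to 0.153). MT-ND5 passed in 9 of 21 alternatives, and not with library size alone (adjusted p 0.0846), upper-quartile factors (0.0526), a mean of at least 50 counts (0.0550) or robust empirical Bayes (0.0558). HR 1, whose mitochondrial genome share was 2.96% against 4.06% and 5.01% in HR 3 and HR 2, weighed in this list, which did not pass without it (adjusted p 0.0904). Of the nuclear genes of respiratory complex I, 0 of 36 rose and 1 fell (camera adjusted p = 0.438), and adjusted p for complexes II and III, complex IV and the ATP synthase were 0.300, 0.782 and 0.776. PINK1, a kinase that marks damaged mitochondria for removal, fell 2.02-fold, from 24.5 ± 2.37 to 12.1 ± 0.0662 CPM (edgeR adjusted p = 0.00182).

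Of 30 proliferation genes, TPX2, AURKA and PLK1 fell, at -0.69, -0.57 and -0.71, and 0 rose, or 4 and 0 adjusted over the list alone (camera adjusted p = 0.0192, and adjusted p = 0.696 with an estimated correlation). Among genes with a mean of at least 50 counts the list did not pass (camera adjusted p 0.0633). TPX2 did not pass without PBS 3 or HR 3 (adjusted p 0.0527 and 0.0522), AURKA without PBS 1, PBS 3 or HR 3 (adjusted p 0.0808 to 0.0870), or PLK1 without PBS 1, PBS 3, HR 1 or HR 3 (adjusted p 0.0718 to 0.118). Of 16 angiogenic and preeclampsia-associated genes, 4 rose and 2 fell, or 5 and 3 adjusted over the list alone (camera adjusted p = 0.376). For this list fry, which does not compare it with other genes, gave an adjusted p of 0.00521 in the upward direction. The vasoconstrictor gene EDN1 rose 16.1-fold, from 0.237 ± 0.153 to 4.04 ± 0.368 CPM, and the pregnancy protease gene PAPPA rose 11.3-fold, from 0.110 ± 0.133 to 1.42 ± 0.529 CPM. PAPPA was barely counted in PBS, so its fold is uncertain, with log2 fold changes of 2.975 to 5.1 over the alternatives. The angiogenic factor and receptor genes FLT1, ENG and PGF did not pass, at log2 fold changes of 0.31, -0.49 and 0.02; ENG passed without pAKK_HR 1 (edgeR adjusted p 0.0361), and FLT1 lay at -0.06 without HR 1.

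The number of genes that changed with H/R depended on single libraries. It was 908 without PBS 1, 772 without PBS 2, 973 without PBS 3, 628 without HR 3 and 3474 without pAKK_HR 1, whose spread enters the shared fit, and 5172 without both HR 1 and pAKK_HR 1, an alternative chosen after the data were seen. Log2 fold changes fell with transcript GC content (Spearman's rho of -0.412 across genes with a mean of at least 4 CPM; genes are not independent replicates), from a median of 0.31 in the fifth of genes with the lowest GC content to -0.20 in the fifth with the highest.

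**Figure D2:**
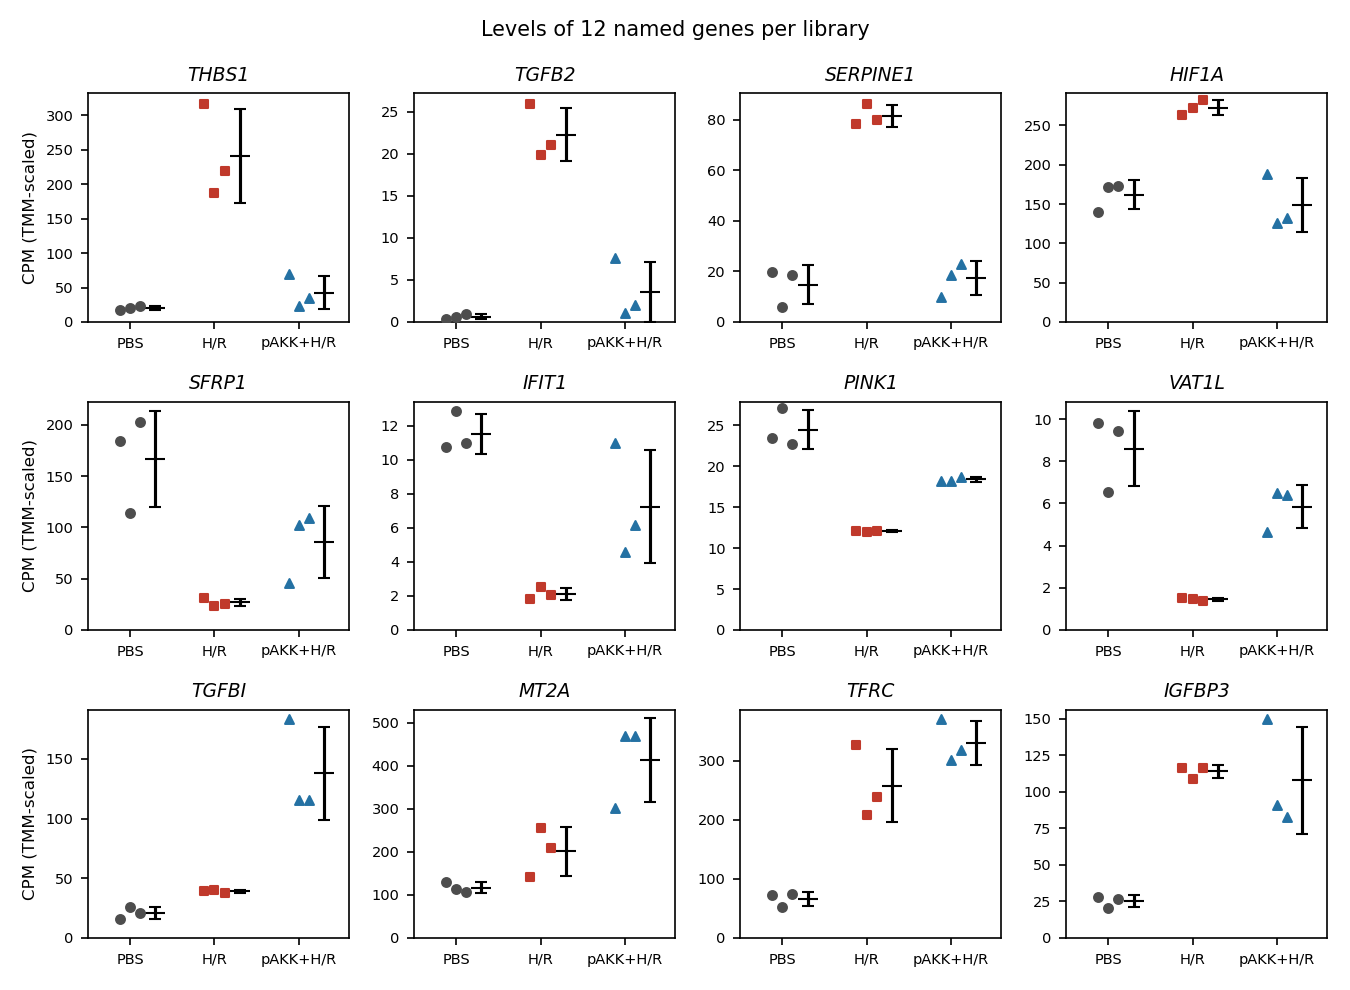
Levels of 12 genes in CPM scaled by TMM, on the vertical axis, by group; each point is a library, and the bar beside each group shows the mean ± SD of its 3 libraries. THBS1, TGFB2, SERPINE1 and HIF1A were higher in H/R than in the other groups, with THBS1 at 20.2, 241 and 42.6 CPM on average in PBS, H/R and pAKK+H/R, while TGFBI was highest in pAKK+H/R at 138 CPM.

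The comparison of pAKK+H/R with H/R asked what the pasteurized bacterium did to cells under hypoxia and reoxygenation. THBS1 was 5.66-fold lower with the bacterium, at 42.6 ± 24.0 CPM against 241 ± 67.8 CPM in H/R (SD, n = 3 per group). SERPINE1 was 4.72-fold lower, at 17.2 ± 6.72 CPM against 81.4 ± 4.35, and CCN2 2.29-fold lower, at 192 ± 29.6 CPM against 441 ± 4.03. SFRP1 was 3.21-fold higher, at 85.8 ± 35.2 CPM against 26.7 ± 3.69, and the matrix adhesion gene TGFBI (ENSG00000120708.12), already higher in H/R than in PBS, was 3.53-fold higher, at 138 ± 39.1 CPM against 39.0 ± 1.43. Without HR 3, SERPINE1 and SFRP1 no longer passed the test (edgeR adjusted p 0.0547 and 0.0683).

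In edgeR's quasi-likelihood test, 933 of 15991 genes (5.83%) changed between H/R and pAKK+H/R, 405 higher and 528 lower with the bacterium, and 113 and 222 of them differed at least 2-fold. Scaling by library size alone split the calls into 183 higher and 688 lower. Genes counted almost only in the H/R libraries led the decreases. NPHS1 had 3 counts over the pAKK+H/R libraries against 432 in H/R, a ratio of 135 with a 95% counting interval of 45.8 to 657. ZAN had 2 counts against 302, a ratio of 141 with an interval of 38.8 to 1170, and CACNA1A 3 against 324, a ratio of 101 with an interval of 34.3 to 493. RYR1 fell at -5.39 on the log2 scale, NIBAN3 at -4.78, RBPJL at -4.67 and the iodide transporter gene SLC5A5 at -3.62. VAT1L rose at 2.00, the adhesion glycoprotein gene VTN at 1.87, the protease inhibitor gene SERPINA1 at 1.96 and the collagen VI gene COL6A3 at 2.19; without HR 3 neither SERPINA1 nor COL6A3 passed (adjusted p 0.0758 and 0.0850), nor did COL6A3 without pAKK_HR 3 (adjusted p 0.0595).

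Of 25 type I interferon response genes, 3 rose with the bacterium and 0 fell, or 7 and 0 adjusted over the list alone, and 23 had a log2 fold change above 0 (camera adjusted p = 3.19e-05, and adjusted p = 0.643 with an estimated correlation). IFIT1 rose at 1.76, IFI6 at 1.19 and IFI35 at 0.82. IFIT1 and IFI6 did not pass without HR 3 (edgeR adjusted p 0.0658 and 0.0778), and IFI35 did not pass without any library other than HR 2 in turn (adjusted p 0.0536 to 0.162). Of 9 replication-dependent histone genes, 0 passed the test of single genes, 2 were lower adjusted over the list alone, and 0 had a log2 fold change above 0 (camera adjusted p = 0.00710, and adjusted p = 0.643 with an estimated correlation). Histone genes are near-identical copies, whose reads can be divided among them. How far the mRNA kit captured their transcripts was not tested. Among genes with a mean of at least 50 counts this list had too few members to test. The interferon and histone lists alone passed when HR 1 and pAKK_HR 1 were both left out, where IFI35 did not (adjusted p 0.0530).

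Of 13 protein genes of the mitochondrial genome, 2 rose with the bacterium and 0 fell, or 8 and 0 adjusted over the list alone (camera adjusted p = 0.000437, and adjusted p = 0.643 with an estimated correlation). MT-ND6 rose at 1.15 and MT-ND5 at 0.98, and neither passed without HR 3 (edgeR adjusted p 0.0798 and 0.0915), nor did MT-ND6 without pAKK_HR 2 (adjusted p 0.0520). In pAKK_HR 1 the mitochondrial genome took 8.35% of the counts, against 5.22% and 4.78% in the other libraries of its group, and in HR 1 2.96%. Of 20 glycolysis genes, 3 rose and 0 fell, also adjusted over the list alone, with ALDOC at 1.63, HK1 at 0.66 and ENO2 at 0.55 (camera adjusted p = 0.00710, and adjusted p = 0.643 with an estimated correlation). ALDOC did not pass without HR 3 (adjusted p 0.0658), HK1 without HR 3, pAKK_HR 2 or pAKK_HR 3 (adjusted p 0.0774 to 0.124), or ENO2 without any PBS library, HR 2, HR 3, pAKK_HR 2 or pAKK_HR 3 (adjusted p 0.0540 to 0.209) or with the GC and length trend removed (adjusted p 0.0743). Of 19 fatty acid oxidation genes, DECR1 rose, at 0.75, and 0 fell, or 6 and 0 adjusted over the list alone (camera adjusted p = 0.0109, and adjusted p = 0.643 with an estimated correlation). DECR1 did not pass without HR 3, pAKK_HR 2 or pAKK_HR 3 (adjusted p 0.0557 to 0.0966). Of 30 proliferation genes, 3 rose and 0 fell, or 6 and 0 adjusted over the list alone, with TPX2 at 0.76, RRM2 at 0.57 and MKI67 at 0.94 (camera adjusted p = 0.00667, and adjusted p = 0.643 with an estimated correlation). TPX2 did not pass without HR 3 (adjusted p 0.0790), RRM2 without any library other than HR 1 and pAKK_HR 1 (adjusted p 0.0517 to 0.144), or MKI67 without any other than HR 1 (adjusted p 0.0658 to 0.216). Neither RRM2 nor MKI67 passed with library size alone (adjusted p 0.0768 and 0.114). Without HR 1, the glycolysis and fatty acid oxidation lists did not pass (camera adjusted p 0.0718 and 0.0802), nor did proliferation without pAKK_HR 1 (adjusted p 0.0710). Without both libraries, the adjusted p of these 4 lists lay between 0.104 and 0.220.

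Of 22 immediate early genes, CCN2 and CCN1 fell with the bacterium, at -1.20 and -0.97, and 0 rose, also 2 and 0 adjusted over the list alone (camera adjusted p = 0.0424, and adjusted p = 0.643 with an estimated correlation). CCN1 did not pass without HR 3 or pAKK_HR 2 (edgeR adjusted p 0.0915 and 0.0682). The list itself did not pass without any 1 library other than pAKK_HR 3 (camera adjusted p 0.0727 to 0.513), nor with scaling by library size alone (adjusted p 0.0504) or among genes with a mean of at least 50 counts (adjusted p 0.0642). Of 20 TGF-beta response genes, 5 fell and 2 rose, or 7 and 3 adjusted over the list alone (camera adjusted p = 0.116). HIF1A fell 1.83-fold, from 273 ± 9.47 to 149 ± 34.1 CPM, and EDN1 fell 6.65-fold, from 4.04 ± 0.368 to 0.593 ± 0.327 CPM. HIF1A did not pass without HR 3, pAKK_HR 2 or pAKK_HR 3 (adjusted p 0.0643 to 0.0850), nor EDN1 without HR 3 (adjusted p 0.0565). Of 19 apoptosis-promoting genes, PMAIP1 fell, at -0.85, and 0 rose, also adjusted over the list alone (camera adjusted p = 0.991), while 0 of 12 apoptosis-opposing genes passed, or 1 lower adjusted over the list alone (camera adjusted p = 0.991). PMAIP1 did not pass without HR 3, pAKK_HR 2 or pAKK_HR 3 (adjusted p 0.0601 to 0.0921) or with the GC and length trend removed (adjusted p 0.0778). PINK1 rose 1.52-fold, from 12.1 ± 0.0662 to 18.4 ± 0.298 CPM, and did not pass without PBS 1, PBS 3, HR 2, HR 3, pAKK_HR 2 or pAKK_HR 3 in turn (adjusted p 0.0534 to 0.143).

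Single libraries weighed more in this comparison than in that of H/R with PBS. The number of genes was 51 without HR 3, 1503 without HR 1, 1936 without pAKK_HR 1, 189 without pAKK_HR 2 and 237 without pAKK_HR 3, and 3816 without both HR 1 and pAKK_HR 1. A fit of the 6 libraries alone gave 284 genes and ended the calls of SERPINA1, HIF1A, PMAIP1, PINK1, IFI6, IFI35, MT-ND5, MT-ND6, MT1E, MT2A, HK1, ENO2, DECR1, TPX2, RRM2, MKI67, CALHM3 and NTNG2 (adjusted p 0.0527 to 0.151). Library size alone ended those of ENO2, DECR1, PINK1, IFI35, RRM2 and MKI67 (adjusted p 0.0542 to 0.119), no filter that of PINK1 (adjusted p 0.0666) and limma-voom that of ADAMTSL1 (adjusted p 0.0649). MKI67 also did not pass with RLE factors, a mean of at least 50 counts or robust empirical Bayes, nor IFI35 with upper-quartile factors (adjusted p 0.0507 to 0.0613). The number of genes was 1716 with DESeq2 and 1736 in edgeR without a filter on low counts.

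The comparison of pAKK+H/R with PBS asked how far cells given both treatments remained from the control. In edgeR's quasi-likelihood test, 9 genes changed and all 9 were higher than in PBS. TGFBI was 6.59-fold higher, at 138 ± 39.1 CPM against 20.9 ± 5.30 (adjusted p = 0.000434), and TFRC 4.99-fold higher, at 330 ± 36.4 CPM against 66.1 ± 12.3 (adjusted p = 0.000434). IGFBP3 was 4.31-fold higher, at 108 ± 36.6 CPM against 25.0 ± 4.21, and DIO2 4.23-fold higher, at 12.5 ± 3.46 against 2.97 ± 1.06. The metallothionein genes MT1E and MT2A were 3.88-fold and 3.54-fold higher, and the adhesion scaffold gene NEDD9 2.43-fold. The others were a long noncoding RNA and a processed pseudogene, HNRNPA1P33, whose reads can be shared with its parent gene. Of the 9, 8 had also risen with H/R. At an unadjusted p under 0.05 there were 988 genes. DESeq2 called 106, of which 50 were higher and 56 lower. Without a filter on low counts edgeR called 158, of which 93 were higher and 65 lower. Limma-voom called 11 higher and 1 lower.

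Of 23 cholesterol synthesis genes, none passed the test over all genes, 16 were lower adjusted over the list alone, and 0 had a log2 fold change above 0 (camera adjusted p = 2.49e-23, and adjusted p = 0.0282 with an estimated correlation). HMGCS1 at -1.20, MSMO1 at -1.18 and LSS at -0.87, all of them enzymes of the pathway, were among the 4 with the smallest p, and these 3 passed with DESeq2 (adjusted p 0.000127, 0.000105 and 7.33e-06). Of 5 genes of the metallothionein list, MT1E and MT2A rose and 0 fell, or 4 and 0 adjusted over the list alone (camera adjusted p = 1.38e-11, and adjusted p = 0.0282 with an estimated correlation). Of 20 TGF-beta response genes, TGFBI rose and 0 fell, or 5 and 0 adjusted over the list alone (camera adjusted p = 9.45e-07, and adjusted p = 0.0282 with an estimated correlation). Another 7 lists passed with the preset correlation, and none of the 7 with an estimated one (adjusted p = 0.305 to 0.589 with an estimated correlation). Among them, genes promoting intrinsic apoptosis had a median log2 fold change of -0.22, with 6 of 19 above 0 and 0 past the test (camera adjusted p = 0.0302), and this list did not pass without PBS 1, pAKK_HR 1 or pAKK_HR 3 (adjusted p 0.0579 to 0.111). HIF targets had a median of 0.17 with 0 of 30 past the test (camera adjusted p = 0.0372) and did not pass without PBS 1, PBS 2, HR 2, HR 3 or pAKK_HR 1 in turn (adjusted p 0.0525 to 0.589). Antioxidant genes regulated by NRF2 were lower (camera adjusted p = 0.000311), as were the integrated stress response and NF-kB lists (0.00423 and 0.0302). Syncytiotrophoblast markers (camera adjusted p = 0.00122) and angiogenic and preeclampsia-associated genes (0.0372, or 0.0229 with fry) were higher. No member of these lists passed over all genes. Without pAKK_HR 1 the stress response, NF-kB and angiogenic lists did not pass (camera adjusted p 0.0548 to 0.207). The angiogenic list also did not pass without PBS 1, HR 2, pAKK_HR 2 or pAKK_HR 3 in turn (camera adjusted p 0.0532 to 0.137). Among genes with a mean of at least 50 counts, neither the NF-kB nor the angiogenic list passed (camera adjusted p 0.0808 and 0.157).

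Without PBS 2 there were 5 genes between pAKK+H/R and PBS, without HR 1 there were 26, without pAKK_HR 1 there were 68, and without both HR 1 and pAKK_HR 1 there were 442, of which 222 were higher and 220 lower. DIO2 did not pass without PBS 1 or PBS 2 (edgeR adjusted p 0.150 and 0.154), MT1E and MT2A without PBS 2 or PBS 3 (adjusted p 0.0513 to 0.0947), or NEDD9 without any PBS library, HR 3 or pAKK_HR 2 (adjusted p 0.0915 to 0.242). In a fit of the 2 groups alone DIO2 and NEDD9 did not pass (adjusted p 0.0664), nor did NEDD9 with library size alone (adjusted p 0.0822).

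**Figure D3:**
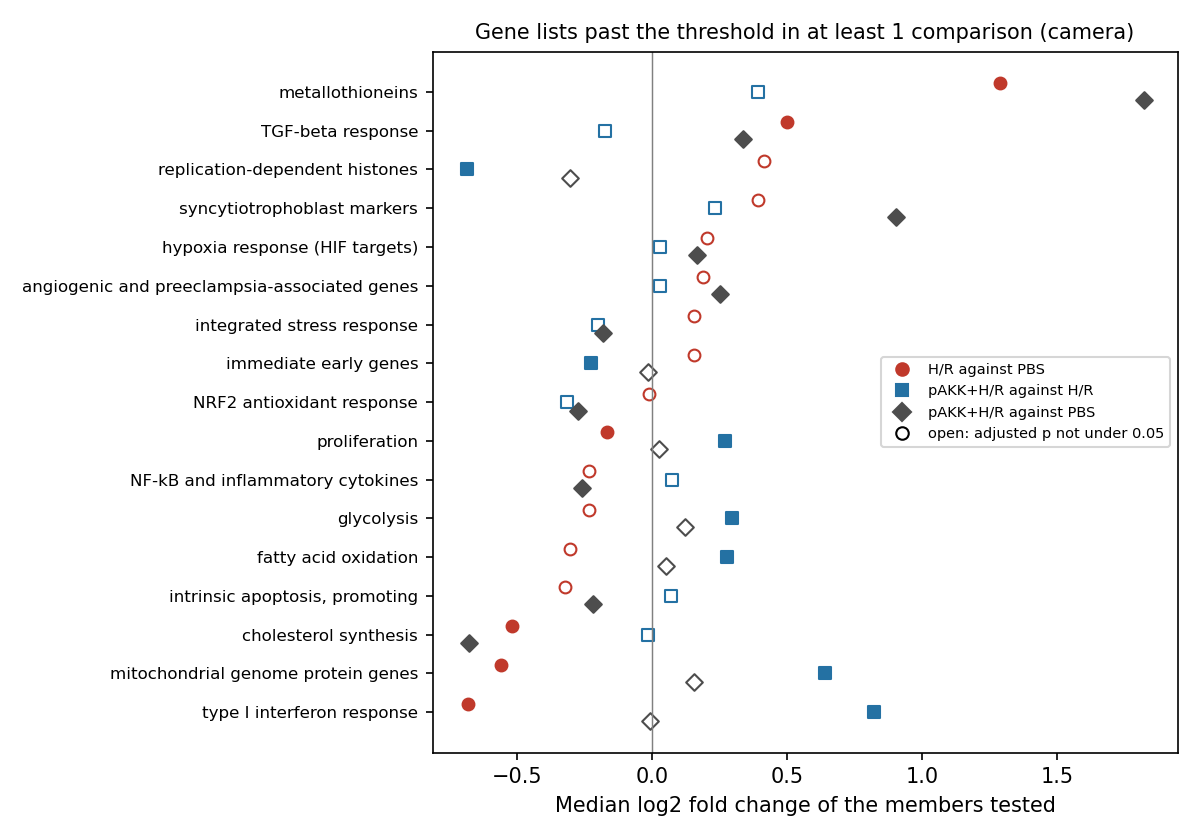
Median log2 fold change of the members of 17 gene lists, on the horizontal axis, in each of 3 comparisons given by marker shape and colour; filled markers passed the camera test with a preset correlation. Cholesterol synthesis was lower in both treated groups than in PBS, at -0.52 and -0.68, and the interferon list was lower in H/R than in PBS at -0.68 and higher in pAKK+H/R than in H/R at 0.82; of these, the cholesterol list at -0.68 alone passed with an estimated correlation.

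Setting both comparisons of the H/R group side by side asked how many genes changed by H/R were moved back in cells given the bacterium. Of the 2009 genes, 764 (38.0%) were: 428 raised by H/R and lower with the bacterium, and 336 lowered by H/R and higher with it. The 428 included 86 of the 290 genes counted almost only in H/R, of which 91 were tested and 90 rose in H/R. Those genes were chosen for being counted in H/R and nearly silent in every PBS and pAKK+H/R library. Their rise and return follow from that choice and give no evidence for an effect of the bacterium. The origin of that set stays open. By the size of both changes, the raised genes included NIBAN3, RYR1 and RBPJL, and the lowered genes CALHM3, VAT1L, ADAMTSL1, NTNG2, SFRP1 and IFIT1. The median log2 difference from PBS of the genes raised by H/R was 0.91 in H/R and 0.19 in pAKK+H/R, and that of the genes lowered was -0.86 and -0.24. TGFBI, MT2A and MT1E, 3 genes in all, moved further in the same direction, with log2 fold changes of 0.90, 0.79 and 1.06 and then 1.82, 1.04 and 0.90. TGFBI did not pass in H/R without PBS 1, PBS 3 or HR 3 (edgeR adjusted p 0.0681 to 0.0881), MT2A without any PBS library, HR 2 or HR 3 (adjusted p 0.0807 to 0.140) or MT1E without PBS 3 (adjusted p 0.0625); in the comparison with H/R, MT2A and MT1E failed without HR 3, pAKK_HR 2 or pAKK_HR 3, and MT1E also without any PBS library or HR 1 (adjusted p 0.0509 to 0.157). Of the lowered genes named here, VAT1L kept its call in both comparisons with any 1 library left out, while SFRP1 and IFIT1 lost that against H/R without HR 3 (adjusted p 0.0683 and 0.0658), and CALHM3, ADAMTSL1 and NTNG2 without HR 3, pAKK_HR 2 or pAKK_HR 3 (adjusted p 0.0595 to 0.103).

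Both comparisons share the H/R libraries, which gives opposite signs by chance. In 50 simulated data sets with no effects the number moved back was at most 1. It was also at most 1 in 50 that kept the H/R effect and set pAKK+H/R at the H/R means. In both kinds at most 2 genes passed between H/R and pAKK+H/R, which caps these counts, so they cannot decide. With the H/R effect kept, a mean of 3340 genes changed by H/R, against 2009 in the data. Noise was drawn separately for each gene, so deviations shared across a library were left out. Lists drawn independently would share 58.6 genes. The simulations leave out the effects of the bacterium and the value of 58.6 leaves out the shared libraries, so part of the excess may come from the shared libraries. Separate H/R libraries were not used for each comparison, since 1 comparison would be left with 1 of the 3. The covariance of the log2 fold changes across genes was -0.453 against a simulated mean of -0.0543 with the H/R effect kept, a difference of -0.399. It was -0.170 among genes with a mean of at least 50 counts and -0.733 to -0.495 with 1 library left out. Genes were filtered anew for each of these values, so they cover other sets of genes than the -0.453. No simulated value was made for those sets. In the full data the correlation was -0.832 against -0.193, or against -0.493 in the data simulated with no effects. The number moved back was 421, 412 and 429 without PBS 1, 2 and 3, 1257 without HR 1, 46 without HR 3, 1523 without pAKK_HR 1, 177 without pAKK_HR 2, 221 without pAKK_HR 3 and 2963 without both HR 1 and pAKK_HR 1.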

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

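All comparisons in this part were chosen after the data were seen. HTSeq's summary lines, which the gene comparisons do not use, gave 4 shares of reads above the highest PBS library. Reads that met no annotated feature made up 6.61% on average in H/R, where each library was at or above 6.16%, against at most 5.58% in PBS. Reads with too low an alignment quality made up 7.97% in H/R and 8.88% in pAKK+H/R, against at most 6.55% in PBS. In pAKK+H/R the lowest library was at 6.55%, and pAKK_HR 1, the library that stood apart from its group, was at 12.6%. Reads ambiguous between genes made up 12.7% in pAKK+H/R, against at most 11.8% in PBS. Where the ranges of 3 libraries against 3 did not overlap, the exact permutation test gave a two-sided p of 0.1, the smallest that this design allows. No explanation was tested for these shares.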

How the results depend on the processing

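Removing the GC trend and leaving out HR 1 and pAKK_HR 1 together were chosen after the data were seen, and the other alternatives were planned. The 143 results for named genes gave 3120 values under alternatives, of which 2764 kept their direction and side of the threshold, 305 no longer passed, 44 came to pass and 7 reversed. Calls of named genes ended most often without HR 3, 58 of the 143, and among alternatives that leave out no single library and set no minimum fold change, in the fit of the 2 groups alone, 27, with library size alone, 10, and with the GC and length trend removed, 9. Those 7 belonged to PGF and FLT1, which had not passed. PGF was at -0.0307 with limma-voom, -0.00722 with no filter and -0.219 to 0.225 with 1 library left out. FLT1 was at -0.0562 to 0.522 with 1 library left out and at -0.0554 without HR 1 and pAKK_HR 1; the cause was not tested. A mean of at least 50 counts gave 4 lists for H/R against PBS, without proliferation, left some named genes untested and left the metallothionein and histone lists with too few members.

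For H/R against PBS, 804 genes had a log2 fold change of at least 1, which only counts a subset, 5172 passed without HR 1 and pAKK_HR 1, and 628 to 3474 with 1 library left out. For pAKK+H/R against H/R there were 1716 with DESeq2, 1736 with no filter, 284 in a fit of the 2 groups alone, 335 with a log2 fold change of at least 1, 3816 without HR 1 and pAKK_HR 1, and 51 to 1936 with 1 library left out. For pAKK+H/R against PBS there were 106 with DESeq2, 158 with no filter, 33 with the GC trend removed, 442 without HR 1 and pAKK_HR 1, and 5 to 68 with 1 library left out. The genes moved back numbered 1342 with DESeq2, 1338 with no filter, 257 with a log2 fold change of at least 1, 2963 without HR 1 and pAKK_HR 1, and 46 to 1523 with 1 library left out. The genes moved further numbered 0 with a log2 fold change of at least 1, 9 without HR 1 and pAKK_HR 1, and 0 to 4 with 1 library left out.

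Lists past camera for H/R against PBS numbered 0 with an estimated correlation and 6 to 10 with 1 library left out. Fry passed 4, dropping the interferon, mitochondrial genome and proliferation lists (adjusted p 0.0692, 0.132 and 0.0502) and adding the angiogenic and preeclampsia list (adjusted p 0.00521). For pAKK+H/R against H/R they numbered 0 with an estimated correlation, 0 with fry, 2 without HR 1 and pAKK_HR 1, and 5 to 8 with 1 library left out. For pAKK+H/R against PBS they numbered 3 with an estimated correlation, 4 with fry, and 6 to 10 with 1 library left out. The covariance of both log2 fold changes was -0.170 with a mean of at least 50 counts, -0.792 without HR 1 and pAKK_HR 1, and -0.733 to -0.495 with 1 library left out. These values cover different sets of genes, since the filter was applied anew each time. Apart from the log2 fold change of at least 1, the cause was not tested.

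DESeq2 kept 99.8% of the 2009 calls and 99.9% of the 933, and RLE size factors kept 98.4% and 96.9%. Library size alone kept 82.2% and 75.9%, the fit of the 2 groups alone 30.2% of the 933, and leaving out HR 3 kept 622 of the 2009 and 5.47% of the 933. On simulated data 43.3% of 2-fold changes between PBS and H/R were called, which limits what 3 libraries per group can show.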

Other observations

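The tests of depth, immune RNA, nearness to PBS, GC content and batch below were chosen only after the result was seen. The splits and the tests of genomic DNA and run-on were not. The gene set that the tests of genomic DNA and run-on use was itself defined after the data were seen. Regrouping the 6 libraries of each comparison gives 10 splits, too few for a share under 0.05. The real splits gave 2009, 933 and 9 genes by edgeR, in 1 of the 10 splits each, and the highest of the others gave 0.

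Single genes of the matrix and of trophoblast invasion passed the test, while their lists did not. Of 21 extravillous trophoblast genes, 2 rose and 8 fell in H/R, or 4 and 8 adjusted over the list alone (camera adjusted p = 0.452). The membrane protease gene MMP14 fell at -1.10 on the log2 scale and the integrin gene ITGA5 at -0.99, while FN1, the fibronectin gene, rose at 2.10. Of 19 stromal genes, 2 rose and 3 fell, or 3 and 4 adjusted over the list alone (camera adjusted p = 0.415), and the collagen genes COL6A2 at -1.31, COL6A1 at -1.10 and COL1A1 at -1.22 fell. With the bacterium, 3 of the 21 rose and 1 fell, or 5 and 1 adjusted over the list alone (camera adjusted p = 0.355), and 4 of the 19 rose and 0 fell, or 5 and 1 adjusted over the list alone (camera adjusted p = 0.223). MMP14 rose at 0.78, ITGA5 at 0.69, COL6A2 at 1.18, COL6A1 at 0.84 and COL1A1 at 0.97, while FN1 did not pass (-0.22). Against H/R, MMP14, ITGA5 and COL6A1 did not pass without HR 3, pAKK_HR 2 or pAKK_HR 3, or COL1A1 without these or HR 2 (edgeR adjusted p 0.0518 to 0.125), while COL6A2 passed with any 1 library left out. Nor did MMP14, ITGA5, COL6A1 and COL1A1 pass in a fit of the 2 groups alone (adjusted p 0.0565 to 0.0900), or MMP14 and COL1A1 with library size alone (adjusted p 0.0577 and 0.0519).

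Antioxidant genes regulated by NRF2 moved both ways in H/R, with 4 of 21 higher and 3 lower, or 6 and 6 adjusted over the list alone (camera adjusted p = 0.944), and the list's median and its mean differed in sign. The cystine transporter gene SLC7A11 rose at 0.90, the drug exporter gene ABCC3 at 2.97 and the glutathione synthesis gene GCLM at 0.83, while the quinone reductase gene NQO1 fell at -0.75. NQO1 did not pass without PBS 1, PBS 3 or HR 3 (edgeR adjusted p 0.0716 to 0.0804), nor did SLC7A11 and GCLM with the GC and length trend removed, at 0.54 and 0.51 (adjusted p 0.111 and 0.0830). With the bacterium 4 were lower and 0 higher, or 7 and 1 adjusted over the list alone (camera adjusted p = 0.105), with SLC7A11 at -1.12 and ABCC3 at -2.71. In pAKK+H/R against PBS, 3 of 21 had a log2 fold change above 0. There 0 passed over all genes and 2 were lower adjusted over the list alone (camera adjusted p = 0.000311, and adjusted p = 0.371 with an estimated correlation). Without HR 3, GCLM did not pass in H/R and ABCC3 did not pass with the bacterium (edgeR adjusted p 0.0611 and 0.0572). The mitochondrial fusion gene OPA1 rose at 0.62 and the mitochondrial transcription factor gene TFB2M at 0.95 in H/R, and both fell with the bacterium, at -0.59 and -0.98. OPA1 did not pass in H/R without PBS 1, PBS 2 or HR 3, or with the bacterium without PBS 3, HR 3, pAKK_HR 2 or pAKK_HR 3, and TFB2M with the bacterium did not without HR 3 (adjusted p 0.0501 to 0.144). With the GC and length trend removed, OPA1 passed in neither comparison, at 0.35 and -0.37 (adjusted p 0.0636 and 0.0775). In a fit of the 2 groups alone, OPA1 did not pass with the bacterium (adjusted p 0.0877).

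Genes counted almost only in 1 group, by thresholds chosen after the data were seen (a mean over 0.5 CPM there and under 0.3 CPM in each other library), numbered 290 in H/R, 2 in PBS and 5 in pAKK+H/R, the H/R genes including NPHS1, ZAN, CACNA1A and RBPJL. After thinning to equal totals H/R had 38.6 times as many as the next group, which argues against depth, and of 3326 other silent genes at least as long as their median, 61.0% had 3 or fewer counts over the H/R libraries, which argues against background in proportion to exon length, though reads that met no feature were also more frequent in H/R (6.61% against at most 5.58% in PBS) and the set had a median GC content of 55.6% against 45.7% in other silent genes. An expressed neighbour lay within 20 kb upstream on the same strand for 15.2% of the set and downstream for 19.2%, against 8.26% and 7.51% of length-matched silent genes. This argues against run-on from such an upstream neighbour for most of the set and leaves it open for the rest. Genes farther away or on the other strand were not searched, and with the strand setting unknown, run-on from them stays open. The level of CD19 rose from 0 to 1.76 CPM, and that of CD79A from 0.655 to 1.46 CPM, but CD74, abundant in B cells, rose by 0.313 times the CD19 level (2.23 to 2.78 CPM), which argues against B cells. HLA-DRA, MS4A1 and PTPRC stood at 0.0192, 0 and 0.252 CPM in H/R. The set also held TYROBP, of the immune marker list, at 0.584 CPM in H/R, though 0 of 6 tested genes of that list passed in H/R. Further immune-associated genes in it were FCER2, ITGAL, ITGAM and LCK, at 1.64, 1.35, 1.05 and 0.619 CPM in H/R. PLVAP and CDH5, of the endothelial marker list, stood at 1.51 and 1.06 CPM. Other immune cells stay open. Background of another kind, RNA of another cell type, release of silencing under H/R, or a factor shared by the 3 H/R libraries may each explain the set and stay open.

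Of the genes changed by H/R, 81.3% had a level nearer PBS than H/R in cells given the bacterium, the treatment that separates these groups. Deviations of the H/R libraries alone, which enter both comparisons, would give this share too, so by this value they and an effect of the bacterium cannot be told apart. Data simulated with no effects, with noise drawn separately for each gene, gave a covariance of -0.0575 to -0.0508, against -0.453. Their number moved back, at most 1 against 764, cannot decide this, since at most 2 genes passed in either comparison there. With the GC and length trend removed from each library, 73.6% of the 764 genes were still moved back, which argues against that trend as the whole cause. A larger deviation common to the H/R libraries stays open, since the labels of 0 libraries name a batch, so that a batch of the H/R libraries and the treatment cannot be told apart.

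The log2 fold changes of H/R against PBS fell with transcript GC content, at a rho of -0.412 across genes, and those of pAKK+H/R against H/R rose with it, at 0.401. With the trend removed, 79.1% of the 2009 genes were still changed in the same direction, which argues against a GC and length bias as their whole cause. By library, the rho of the deviation from the mean of all libraries with GC content was -0.291, 0.0055 and -0.274 in HR 1 to 3, 0.261, 0.170 and 0.113 in PBS 1 to 3, and -0.271, 0.319 and 0.363 in pAKK_HR 1 to 3. The H/R libraries lay below the PBS libraries, HR 2 by least, and pAKK_HR 1 lay apart from its group. A change in library preparation and an effect of H/R on GC-poor transcripts may each give the trend itself, and neither was tested.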
